A study of Homo sapiens with 8 samples.

How the data were processed

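Messenger RNA levels were measured by RNA sequencing in primary human mammary epithelial cells, the epithelial cells of the breast grown in culture. Per the labels' protocols, the cells were held in medium without supplements for 36 h and then exposed for 12 h to adenovirus at a multiplicity of infection of 50. The virus carried either green fluorescent protein (GFP) or ABCB1, with 4 libraries of each. Libraries were made with a directional (strand-keeping) kit and read from both ends, per the labels.

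The values deposited by the authors are in TPM (a transcript level corrected for length and scaled so that each library has the same total) for 19371 genes in 8 libraries. The unit was inferred from the values, which have at most 2 decimals and sum to between 999999.11 and 1000000.63 in each library, and is not named in the sources used here. The submitters' processing notes name FastQC, Trimmomatic 0.38, STAR 2.2.1, RSEM 1.3.1 and the genome build hg19, with no settings given in the sources used here. TPM keeps no read totals, so the depth of each library is unknown, no whole reads could be recovered and no counting interval is given. A change in a very abundant transcript shifts the TPM of all others. RSEM divides reads that fit several genes among them, so single values of near-identical genes such as the histones or SMN1 and SMN2 are uncertain.

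The groups were ABCB1 and GFP, taken from the labels, and the only comparison was ABCB1 against GFP. The labels do not state that the replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. No library held the same values as another (0 identical pairs), and every sample column was used. Genes with at least 1 TPM in at least 4 libraries were tested (12027 genes), and 7344 genes were left out. The test was limma 3.58.1 (lmFit and eBayes without trend or robust settings) in R 4.3.3 on log2(TPM + 1), with no replicate block and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes. ABCB1 itself was also compared with an exact two-sided permutation test.

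The 32 gene lists were fixed before the data were examined, and 29 had the 3 tested members needed for a list test. Of 819 members given, 805 were found in the table, 49 of them under another symbol from the RefSeq gene table of GRCh38.p14, which was used for names only. No coordinates are printed, because that assembly differs from the build in the submitters' processing notes. Lists were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 29 lists. Beside it stand camera with a correlation estimated from the data and fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes. ABCB1 was left out of every list test.

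Named genes followed a rule fixed before the data were examined. ABCB1 came first. Next came the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 1 TPM in the higher group and no overlap between the groups. From each list past the list test came the 3 members past the threshold with the smallest p, and from each other list the 1 such member. XIST and Y-linked genes were never named, and 1 gene that the rule names is not reported here. Other genes named below were chosen after their values were seen.

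The scripts were tested on simulated data for the comparison of ABCB1 with GFP, with 12027 genes of which 200 were changed. The test recovered 68% of genes changed by 0.25 on the log2 scale, 92% at 0.5, 96% at 1 and 100% at 2, with 10 false calls among 188. In simulated lists of 25 independent genes, 3% of 200 unchanged lists reached an unadjusted p under 0.05 with the preset correlation and 1.5% with the estimated one. All 50 lists shifted by 0.3 reached it with both (100%). Among the lists that passed camera below, the estimated correlation between genes ran from 0.04 (histones) to 0.51 (immediate early genes). The simulated rates therefore do not carry over to lists with correlated genes. The simulation also changed far fewer genes than were called in the data.

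Alternatives were a replicate block, leaving out each library, quantile normalization, centring each library on its median, no filter on low values, a minimum of 5 TPM, limma with trend and robust settings, ABCB1 left out of the table, pseudocounts of 0.1 and 0.01, an adjusted p of 0.01 and a change of at least 2-fold. A correction for GC content and transcript length was added after seeing the data. It subtracted from each library a loess trend (span 0.3) on GC share and log2 length, taken from GENCODE 29 transcripts with Python 3.11.15, and 98.8% of tested genes had both values. Figures were drawn with matplotlib 3.10.9.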

Results

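The data are gene-level TPM values from 8 RNA libraries of primary human mammary epithelial cells, 4 exposed to an adenovirus carrying GFP and 4 to an adenovirus carrying ABCB1. ABCB1 encodes P-glycoprotein, a membrane pump that exports many chemotherapy drugs. The series title concerns tepoxalin, an inhibitor of cyclooxygenase and 5-lipoxygenase, in breast cancer cells with high ABCB1, and the libraries analysed here carry no drug label. Between 11897 and 12078 genes reached 1 TPM per library, and the 10 most abundant genes held 11.6% to 13.5% of the total. Read depth is unknown, since TPM does not keep it. Group values below are mean TPM ± SD (n = 4), with GFP first, and fold changes are ABCB1 minus GFP on the log2(TPM + 1) scale. They come from limma with Benjamini-Hochberg adjustment.

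The comparison asks which transcripts differ between epithelial cells given ABCB1 and cells given a control protein. The ABCB1 virus delivers that gene, so its transcript level serves as a check of the labels. Transcripts from the virus were assumed to be counted under ABCB1. ABCB1 rose from 1.815 ± 0.0465 to 5608.6 ± 473 TPM, a ratio of 3090.2. Its log2 fold change was 10.96 (SE 0.058, limma adjusted p = 6.0e-15). The libraries labelled ABCB1 held 5141.95 to 6103.03 TPM of it, or 0.514% to 0.61% of all TPM, and those labelled GFP 1.75 to 1.86 TPM. An exact two-sided permutation test over 70 assignments gave p = 0.0286, the smallest it can give. ABCB4, the related gene beside ABCB1, was listed at 0 to 0.04 TPM, and RUNDC3B, whose locus overlaps that region, at 0.58 to 0.93 TPM.

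With ABCB1 included, 5029 of 12027 tested genes (41.8%) changed, 2738 upward and 2291 downward. Most shifts were small. The median log2 fold change was 0.29 among genes that rose and -0.21 among those that fell. A change of at least 2-fold was found for 127 genes that rose and 0 that fell, and for 187 and 202 that rose with pseudocounts of 0.1 and 0.01 (0 fell with either). The groups did not overlap for 4924 genes (40.9%, against 2.86% by chance). Upward calls were 54.4% of the total, and 42% of 5743 calls after quantile normalization, 42.5% of 5737 after centring each library on its median and 40.7% of 5697 after correction for GC content and length. Correlations of log2 values were 0.9976 to 0.9983 among GFP libraries, 0.9948 to 0.9981 among ABCB1 libraries and 0.9824 to 0.9921 between groups. The first principal component held 72.4% of the variance and separated the groups. ABCB1 replicate 4 stood apart on the second (10.5%), at -13.06 against 1.20 to 8.07 for the other ABCB1 libraries.

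**Figure D1:**
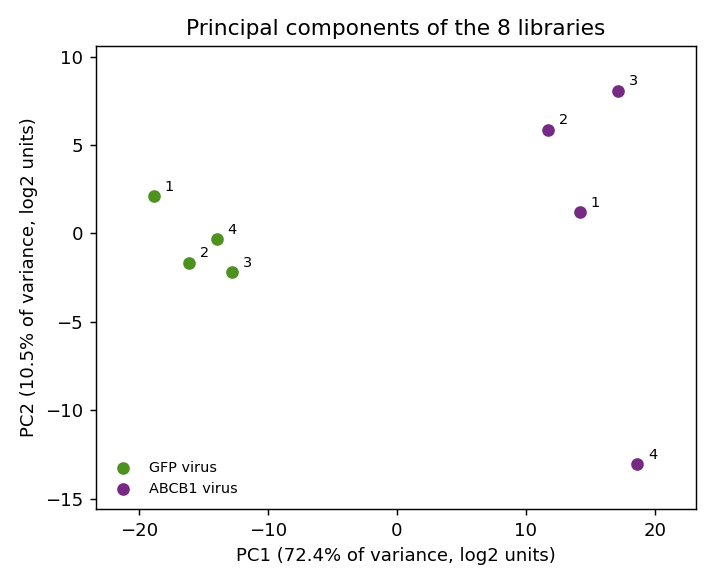
Principal components of log2(TPM + 1) over the 12027 tested genes, 1 point per library, numbered by replicate; the axes give each component's score and its share of the variance. The groups separate along the first component (72.4%), and ABCB1 replicate 4 lies at -13.06 on the second.

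The 6 largest rises after ABCB1 were in CXCL2, SMN2, HIST1H2BF, DDIT3, CXCL3 and KRTAP19-1. CXCL2, a chemokine that attracts neutrophils, went from 36.5 ± 12.5 to 285 ± 59.9 TPM, a log2 fold change of 2.97 (SE 0.23, limma adjusted p = 2.1e-05). CXCL3, a close paralog that can share reads with CXCL2, rose by 2.15. DDIT3, which encodes the stress-induced transcription factor CHOP, rose from 16.1 ± 1.61 to 85.0 ± 7.81 TPM (log2 2.33, SE 0.080, limma adjusted p = 3.2e-07). HIST1H2BF, a histone H2B gene, rose from 1.48 ± 0.893 to 12.4 ± 2.14 TPM, and KRTAP19-1, a keratin-associated protein gene, from 23.3 ± 5.60 to 103 ± 24.2 TPM. SMN2 rose by 2.72, and its call was lost with limma's trend and robust settings (adjusted p = 0.051). SMN2 shares nearly all its sequence with SMN1, and the sum of both was 48.1 ± 2.44 and 60.9 ± 1.61 TPM. Falls were smaller. ALDH1B1, a mitochondrial aldehyde dehydrogenase, fell by 0.70 (50.7 ± 3.22 to 31.4 ± 6.50 TPM). CTGF, a secreted growth factor of the matrix, fell by 0.67 (745 ± 36.2 to 473 ± 83.5 TPM, limma adjusted p = 0.0014). EPPK1, the keratin-binding epiplakin, fell by 0.66. HPS6, needed for lysosome-related organelles, fell by 0.65. The translation initiation factor gene EIF5 and SH3BP5L each fell by 0.64.

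**Figure D2:**
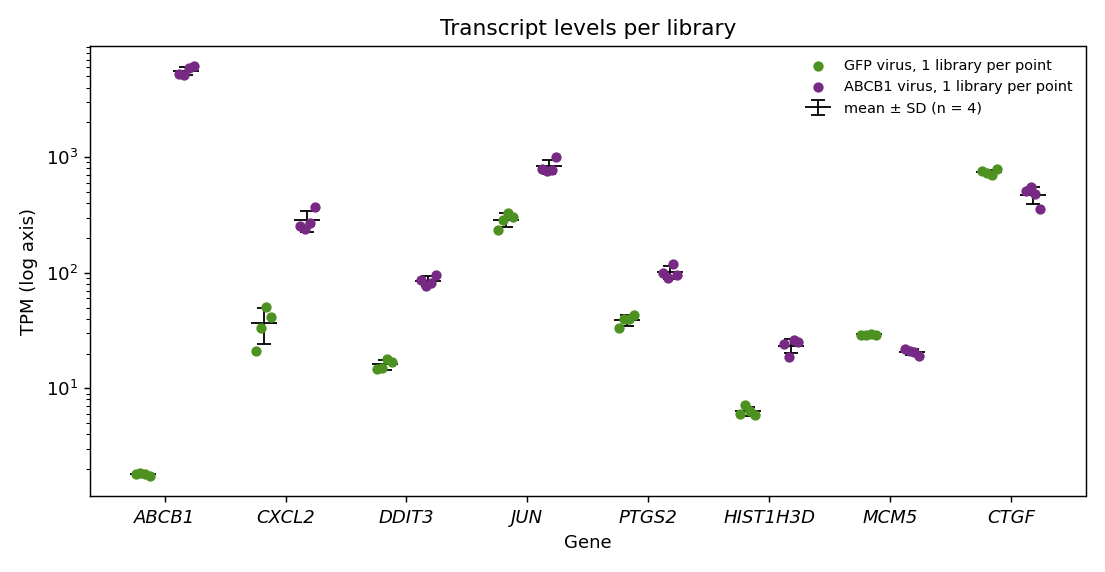
TPM of 8 genes on a log axis, 1 point per library, with GFP libraries at the left and ABCB1 libraries at the right of each gene; bars give the mean ± SD (n = 4). ABCB1 lies at 1.75 to 1.86 TPM with GFP and 5141.95 to 6103.03 with its own virus. In each of the 8 genes the groups do not overlap, which the rule for naming genes required or favoured.

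Of the 29 lists tested, 7 passed camera with the preset correlation, 5 upward and 2 downward. None (0) passed with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.129, and 15 passed by fry. Of the 35 ways to split the 8 libraries into 4 and 4, 24 put at least 7 lists past camera's threshold, so the number of lists passing does not separate the real grouping from others. The counts of members below come from the test of each gene. Markers of HEK293 cells, a line used to grow adenovirus, summed to 99.2 ± 4.43 TPM with GFP and 154 ± 8.18 with ABCB1, higher beside the lists described as rising. PEG10 (52.2 to 88.5 TPM) and NEFM carried that sum, while NEFL and HOXA9 did not pass (log2 -0.04 and -0.11) and HOXA10 fell by 0.24. Fibroblast markers summed to 537 ± 11.9 and 492 ± 16.3 TPM, lower beside the lists described as falling.

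Most tested members of the inflammatory and immediate early gene lists rose. In the list of NF-kB targets and cytokines, 22 of 25 tested members rose, 0 fell and 3 did not pass (23 and 0 adjusted over the list alone). CSF2, a growth factor for myeloid cells, rose from 1.45 ± 0.523 to 6.99 ± 0.835 TPM, and the cytokine gene IL1A from 7.93 ± 0.832 to 17.3 ± 1.44 TPM. The list gave a camera adjusted p = 4.2e-10, with adjusted p = 0.368 with an estimated correlation. Among 27 immediate early genes, which respond to stimuli without new protein synthesis, 22 rose, 1 fell and 4 did not pass (22 and 2 adjusted over the list alone). JUN, a subunit of the AP-1 transcription factor, rose from 288 ± 41.4 to 834 ± 117 TPM (log2 1.53), the nuclear receptor gene NR4A3 from 1.39 ± 0.327 to 4.10 ± 0.226 TPM and FOSL1 by 0.64, while CTGF was the member that fell. That list had a camera adjusted p = 5.7e-09 and adjusted p = 0.648 with an estimated correlation. Targets of the ERK kinase pathway rose for 17 of 23 members, with 1 that fell and 5 that did not pass (18 and 1 adjusted over the list alone). AREG, a ligand of the EGF receptor, went from 419 ± 31.1 to 890.2 ± 47.1 TPM (log2 1.09), PHLDA1 rose by 1.13 and SPRY4, a feedback inhibitor of the pathway, by 0.77. Camera gave adjusted p = 1.5e-06, and adjusted p = 0.368 with an estimated correlation.

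Targets of the tumour suppressor p53 rose for 14 of 28 members, with 1 that fell and 13 that did not pass. MDM2, which marks p53 for degradation, rose from 22.8 ± 0.362 to 38.6 ± 2.61 TPM (log2 0.73), the nuclease gene AEN by 0.78 and the death receptor gene TNFRSF10B by 0.65. Camera gave adjusted p = 0.00017 for the list, and adjusted p = 0.368 with an estimated correlation. The apoptosis list did not pass (camera adjusted p = 0.102), with 14 of 31 members higher, 8 lower and 9 not past the threshold. Its member PMAIP1, a promoter of cell death, rose by 1.14. In the unfolded protein response list, DDIT3 and 7 other members of 24 rose, 0 fell and 16 did not pass (camera adjusted p = 0.0595). ATF4 targets were split, with 6 of 27 higher, 6 lower and 15 not past the threshold (7 and 6 adjusted over the list alone, camera adjusted p = 0.828). The ATF4 list's median was -0.0017 and its mean 0.13, and ATF4 itself rose from 442 ± 22.4 to 673 ± 53.1 TPM. Of 19 heat shock genes, 5 rose, 1 fell and 13 did not pass (camera adjusted p = 0.0626), and the small chaperone gene HSPB8 rose by 0.53. The unfolded protein and heat shock lists passed without ABCB1 replicate 4 (camera adjusted p = 0.00758 and 0.0124) and with quantile normalization (0.0456 and 0.0203), and the heat shock list with no filter on low values (0.0287).

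Among 19 tested replication-dependent histone genes, whose transcripts normally peak in S phase, 15 rose, 0 fell and 4 did not pass (16 and 0 adjusted over the list alone). HIST1H3D rose from 6.35 ± 0.595 to 23.4 ± 3.36 TPM (log2 1.73) and HIST1H2BG from 9.50 ± 1.58 to 27.7 ± 3.95 TPM (log2 1.45). The list's median log2 fold change was 0.81, with camera adjusted p = 1.3e-06 and adjusted p = 0.129 with an estimated correlation. Of 34 genes of the G1/S transition and DNA replication, 15 fell, 3 rose and 16 did not pass (16 and 3 adjusted over the list alone). MCM5 and MCM2, subunits of the replicative helicase, fell from 29.2 ± 0.381 to 20.6 ± 1.07 TPM and from 19.0 ± 0.488 to 13.2 ± 1.35 TPM, whereas GINS3, of the same helicase complex, rose by 0.55. That list gave camera adjusted p = 0.0095, adjusted p = 0.713 with an estimated correlation and fry adjusted p = 0.0583. The G2/M list did not pass (camera adjusted p = 0.291), with 9 of 34 lower, 4 higher and 21 not past the threshold, and the mitotic motor gene CENPE rose by 0.80.

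Of 37 oxidative phosphorylation genes, 13 fell by small amounts, 0 rose and 24 did not pass (5 lower adjusted over the list alone). The complex I genes NDUFA9 and NDUFB10 fell by 0.20 and 0.13. Camera gave adjusted p = 0.0135, adjusted p = 0.682 with an estimated correlation and adjusted p = 0.0545 without GFP replicate 2. Of 48 ribosomal protein genes 4 rose, 0 fell and 44 did not pass (0 adjusted over the list alone, camera adjusted p = 0.522). RPS24 rose by 0.12 (limma adjusted p = 0.018). That call was lost with the replicate number as a block (limma adjusted p = 0.0544), without GFP replicate 1 (0.0512), with quantile normalization (0.119), with median centring (0.0707) and with the GC and length correction (0.14). Cholesterol synthesis genes had 9 of 25 higher, 4 lower and 12 not past the threshold (camera adjusted p = 0.522), and the sterol carrier gene STARD4 rose by 0.42. That list's median was -0.02, its mean 0.09 and its test upward. Fatty acid synthesis had 1 of 20 higher, 4 lower and 15 not past the threshold (camera adjusted p = 0.424), and AGPAT2 fell by 0.22. Hypoxia and glycolysis genes went both ways, with 10 of 30 higher, 9 lower and 11 not past the threshold (camera adjusted p = 0.82), a median of -0.06 and a mean of 0.16. Its member ANKRD37 rose by 0.62.

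**Figure D3:**
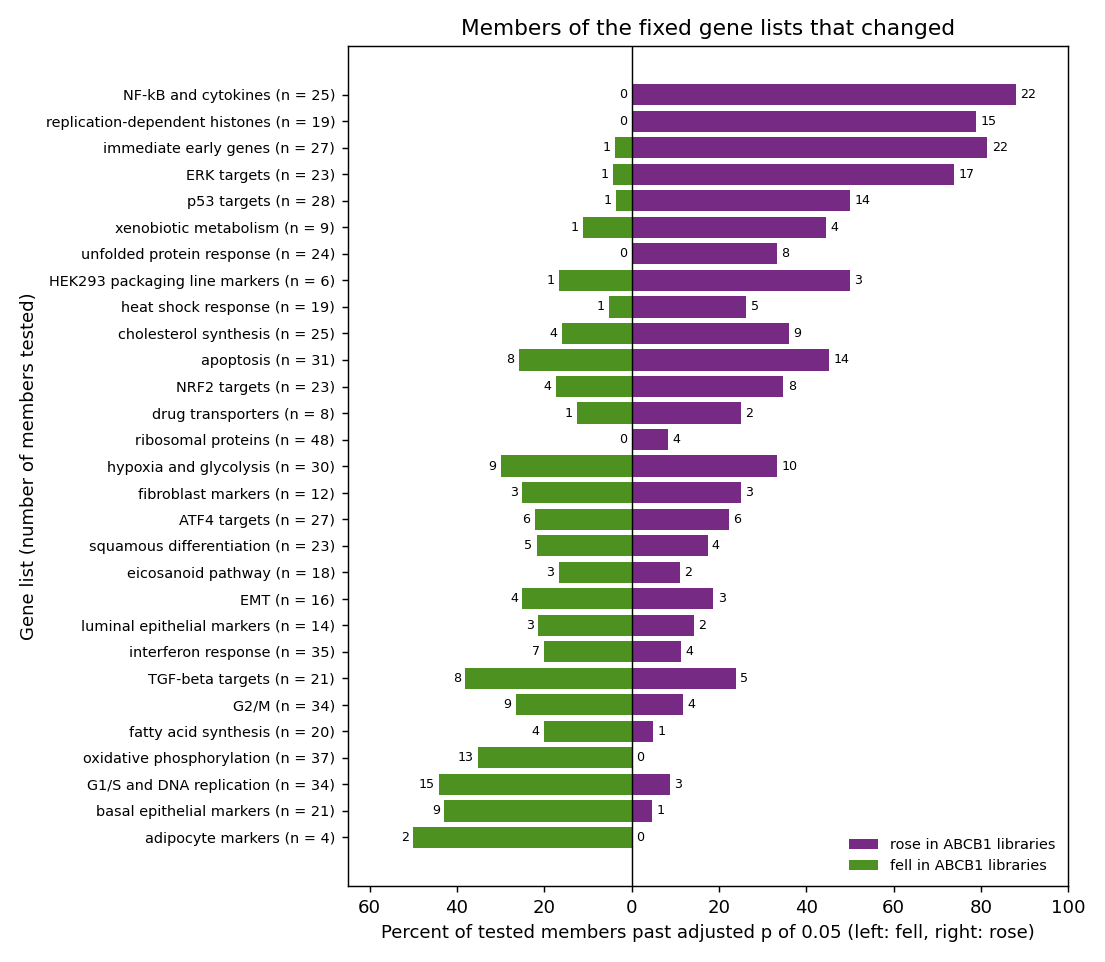
Percent of tested members that rose (right) or fell (left) past a limma adjusted p of 0.05 in each of the 29 tested gene lists, with the number of genes beside each bar and the number tested in each label. NF-kB targets and cytokines had 22 of 25 members that rose, and oxidative phosphorylation had 13 of 37 that fell.

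Drug handling and interferon genes did not pass as lists in camera with the main settings (the filter, scaling and preset correlation used throughout). Apart from ABCB1, 2 of 8 tested drug transporter genes rose, 1 fell and 5 did not pass (camera adjusted p = 0.825). They were ABCC5 (9.51 to 13.7 TPM, log2 0.49), ABCC3 (log2 0.23) and ABCA3, which fell by 0.24, all named after their values were seen. In the eicosanoid pathway, which makes prostaglandins and leukotrienes, 2 of 18 members rose, 3 fell and 13 did not pass (camera adjusted p = 0.533, median -0.02, mean 0.04, test downward). PTGS2, which encodes cyclooxygenase-2, rose from 38.9 ± 4.29 to 101 ± 12.9 TPM (log2 1.36, limma adjusted p = 1.6e-05). Xenobiotic metabolism had 4 of 9 members higher, 1 lower and 4 not past the threshold (camera adjusted p = 0.233), with TIPARP, a target of the aryl hydrocarbon receptor, up by 0.76. NRF2 targets had 8 of 23 higher, 4 lower and 11 not past the threshold (camera adjusted p = 0.522), and the ferritin light chain gene FTL rose from 1542.8 ± 171 to 2691 ± 259 TPM. Of 35 interferon-stimulated genes, 7 fell, 4 rose and 24 did not pass (6 and 3 adjusted over the list alone), and IFIT5 fell by 0.33. The interferon list gave camera adjusted p = 0.0571. It passed without ABCB1 replicate 4 (camera adjusted p = 0.000577), with the replicate number as a block (0.0274), with no filter on low values (0.0463) and with ABCB1 left out of the table (0.0447).

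Cell identity lists did not pass with the main settings either. Of 21 basal epithelial markers 9 fell, 1 rose and 11 did not pass (camera adjusted p = 0.0843). That list passed with no filter on low values (camera adjusted p = 0.0437) and by fry (adjusted p = 0.017). The member that rose was TP63, the master regulator of basal epithelium, from 129 ± 5.87 to 176 ± 14.8 TPM. Luminal markers had 2 of 14 higher, 3 lower and 9 not past the threshold (2 and 2 adjusted over the list alone, camera adjusted p = 0.828, median -0.02, mean 0.04, test downward), and the higher ones included AREG. Squamous differentiation had 4 of 23 higher, 5 lower and 14 not past the threshold (camera adjusted p = 0.828, median 0.0056, mean 0.08, test downward), and CRCT1 rose by 0.88. TGF-beta targets had 5 of 21 higher, 8 lower and 8 not past the threshold (6 and 9 adjusted over the list alone, camera adjusted p = 0.522), and the smooth muscle actin gene ACTA2 fell from 308 ± 13.6 to 208 ± 16.5 TPM. Genes of the epithelial-mesenchymal transition had 3 of 16 higher, 4 lower and 9 not past the threshold (camera adjusted p = 0.543, median -0.05, mean 0.02, test downward), and the transcription factor gene SNAI2 rose by 0.91.

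Markers of leukocytes, endothelial cells and adipocytes were mostly low. Those of fibroblasts were not, with sums of 537 ± 11.9 TPM with GFP and 492 ± 16.3 with ABCB1. HEK293 markers summed to 99.2 ± 4.43 and 154 ± 8.18 TPM. Fibroblast markers had 3 of 12 higher, 3 lower and 6 not past the threshold (3 and 6 adjusted over the list alone, camera adjusted p = 0.543), and FAP rose by 0.30. Adipocyte markers had 2 of 4 lower and 2 not past the threshold (camera adjusted p = 0.106), with PLIN4 down from 3.76 ± 0.259 to 2.82 ± 0.266 TPM. Endothelial markers had 2 tested members, of which EGFL7 fell by 0.38. The leukocyte list had 1 tested member, which did not pass, and its 19 genes summed to 22.4 ± 0.755 and 21.7 ± 2.51 TPM. The HEK293 markers had 3 of 6 higher, 1 lower and 2 not past the threshold (camera adjusted p = 0.256). Of its 12 genes, 5 were at 1 TPM or more in every GFP library, and NEFM, a neurofilament gene, rose from 22.8 ± 1.56 to 42.6 ± 3.17 TPM. The 13 mitochondrially encoded genes were not analysed here. Where no count adjusted over the list alone is given, it equalled the count over all genes, except that ERG among the endothelial markers passed only over its list (log2 0.13).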

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

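The tests of S phase, leukocyte RNA, virus dose and a shared batch or virus stock were chosen after the results were seen, and the correction for GC content and length was added after seeing the data.

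In 5 of 104 groups of 4 libraries of the named genes, 1 library lay far from the other 3, and chance gives about 1 in 20. ATF4 was at 752.26 TPM in ABCB1 replicate 3 against 643.96 to 650.1 in the others. AGPAT2 was at 70.45 TPM in ABCB1 replicate 1 against 72.74 to 73.13. JUN was at 1009.25 TPM in ABCB1 replicate 4 against 765.18 to 787.39. CRCT1 was at 31.07 TPM in GFP replicate 1 against 37.29 to 37.75. NEFM was at 47.33 TPM in ABCB1 replicate 3 against 40.52 to 41.5.

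The first pattern weighed is the breadth of the change, 5029 of 12027 genes. Of 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the real split. The highest of the others gave 0. Those splits mix the groups and so carry the real difference in their spread, which keeps their counts low. A share of 1 in 35 is also the smallest that this test can give. The replicates may be technical, so the test cannot decide whether a chance difference between cultures gave the count. After correction for GC content and length, 89.3% of the calls (4490 genes) kept their call and sign, which argues against that bias as the whole cause. A batch or virus stock shared by each group cannot be told apart from an effect of ABCB1, because the component with 72.4% of the variance separates the groups completely and the labels name no batch. For the count of lists, 24 of 35 splits gave 7 or more lists and the highest other gave 16. Some of those splits hold most GFP libraries on the same side and so keep part of the real difference. They are no clean reference for chance, which that count cannot exclude.

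The second pattern is the rise of replication-dependent histone genes. Reads moved between near-identical histone genes are argued against by the summed TPM of 70 histone genes, which was 504 ± 46.8 with GFP and 990 ± 89.2 with ABCB1, a ratio of 1.96 with no overlap. The list's median was 0.72 after the GC and length correction, from 0.81 before, with camera adjusted p = 2.8e-07 after it, and adjusted p = 0.129 with an estimated correlation before it. A larger share of cells in S phase stays open: 15 of 34 G1/S members fell, 3 rose and 16 did not pass, but that list was lost with an estimated correlation (adjusted p = 0.713) and by fry (0.0583). An effect of ABCB1, a batch and a difference in how histone transcripts end or were captured stay open as hypotheses, and the last was not tested.

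The third pattern is the rise of NF-kB targets and cytokines. Leukocyte RNA is argued against by the leukocyte list, whose summed level changed by -0.68 TPM while CXCL2 rose by 248 TPM, 1 of its 19 genes (CD68) was at 1 TPM or more in every GFP library, and PTPRC, LYZ, TYROBP, CD14, FCER1G and CD3E were at 0.56 TPM or less in every library. The list's median was 0.62 after the GC and length correction, from 0.71 before (camera adjusted p = 3.3e-11 after it, and adjusted p = 0.368 with an estimated correlation before it). A higher dose of virus in the ABCB1 cells stays open. Of 35 interferon-stimulated genes 7 fell and 4 rose, where 2291 of all 12027 tested genes fell and 2738 rose. The interferon list did not pass camera with the main settings (adjusted p = 0.0571), and a dose that acts by other routes may leave no mark on it. An effect of ABCB1 itself also stays open and was not separated from a difference between virus stocks.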

How the results depend on the processing

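The GC content and length correction was chosen after seeing the data, and the other alternatives were planned. Genes changed numbered 5029, against 3046 at an adjusted p of 0.01 and 127 with at least a 2-fold change, both stricter by construction. Leaving out 1 library gave 3973 to 5205, and the other settings 4452 to 5743. ABCB1 kept its call in every setting run, with log2 fold changes of 10.89 to 11.58, and 10.91 to 11 with 1 library left out. Lists past the threshold numbered 7, against 0 for camera with an estimated correlation and 15 by fry, a test that does not compare a list with other genes, which added the unfolded protein, heat shock, NRF2, xenobiotic, apoptosis, basal, luminal, adipocyte and HEK293 lists. The count was 6 to 10 with 1 library left out and 7 to 10 elsewhere. Of the lists past the threshold, oxidative phosphorylation was lost without GFP replicate 2 (adjusted p = 0.0545) and G1/S by fry (0.0583). Named genes kept direction and call in 908 of 914 checks, apart from RPS24 under 5 settings and SMN2 under 1. They were chosen for small p or large changes, so that share does not describe all calls. Of all 5029 calls, 78.1% kept call and sign without GFP replicate 1, the lowest share of any setting. The replicate block kept 86.2% and a pseudocount of 0.1 kept 97.1%, the highest. The list test turned direction, with no call under camera, in these cases (median log2 fold change of the list), and the cause was not tested. Luminal markers turned by fry (-0.0195, adjusted p = 0.0494), without GFP replicate 3 or ABCB1 replicate 2 (-0.0535 to -0.0190 with 1 library left out), with quantile normalization (-0.0463), at a minimum of 5 TPM (0.0062) and with the GC correction (-0.0785). Squamous genes turned by fry (0.0056), without GFP replicate 2 or 3 or ABCB1 replicate 2 (-0.0302 to 0.0854 with 1 library left out), with median centring (-0.0274) and with the GC correction (0.0151). ATF4 targets turned without GFP replicate 4 or ABCB1 replicate 3 (-0.0560 to 0.0610 with 1 library left out), ribosomal proteins without ABCB1 replicate 4 (0.0060 to 0.0342 with 1 library left out) and with quantile normalization (-0.0159), and hypoxia genes with no filter (-0.0598). With the replicate number as a block 4475 genes, 8 lists and a log2 fold change of 10.96 for ABCB1 resulted. Deviations of libraries with the same number correlated at 0.014, -0.088, 0.025 and 0.11, and 1 of 4 ABCB1 libraries correlated best with its own number. These values gave no sign that the numbers pair the samples, but so few pairs cannot exclude it, and the labels leave it open. Count-based alternatives (other size factors, a count model, voom) were not run because the values are TPM, and list tests were not run with trend and robust settings. Depth is unknown, so its limit on low genes cannot be given.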

Other observations

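The 4 gene families below, and the tests of them, were chosen after the data were seen, and members seen before were left out of each test.

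Of 23 actin cytoskeleton genes, 12 fell, 0 rose and 11 did not pass, with a median log2 fold change of -0.18 (camera adjusted p = 4.3e-05 over the 4 families, adjusted p = 0.368 with an estimated correlation). ACTG1, a cytoplasmic actin, fell from 12150.0 ± 212 to 9592 ± 515 TPM, and the crosslinker ACTN1 from 1276 ± 57.6 to 927 ± 89.0 TPM. The calponin gene CNN2 went from 536 ± 27.0 to 394 ± 16.9 TPM and the focal adhesion gene ZYX from 538 ± 26.4 to 420 ± 27.7 TPM. The median was -0.17 after quantile normalization, -0.21 after centring and -0.20 after the GC correction. Fibroblast markers were also lower in sum, at 537 ± 11.9 TPM with GFP and 492 ± 16.3 with ABCB1, with log2 fold changes of -0.25 for COL1A1 and -0.29 for COL1A2, but 3 of 12 markers higher. Actins are close paralogs that can share reads, so their single values are uncertain. The hypothesis that the family falls as a group passed its test with the preset correlation only.

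Of 9 ATF, MAF and BATF genes apart from MAFF, which encode partners of JUN and FOS in AP-1, 7 rose, 0 fell and 2 did not pass (median 0.20, camera adjusted p = 0.00765, adjusted p = 0.368 with an estimated correlation). MAF rose from 41.0 ± 4.27 to 72.1 ± 12.0 TPM and MAFG from 22.3 ± 1.19 to 35.2 ± 3.16 TPM, while MAFF, seen before the test, went from 97.1 ± 15.6 to 338 ± 43.6 TPM. The median stayed at 0.16 to 0.17 under the 3 other scalings.

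A rise of the SR splicing factors and their CLK kinases as a family, proposed because CLK1 rose from 21.8 ± 3.04 to 65.7 ± 5.14 TPM, missed the threshold (camera adjusted p = 0.325), which does not show that the rest were unaffected. Of 18 other members 6 rose, 2 fell and 10 did not pass. The kinase genes CLK4, CLK2 and CLK3 rose by 0.98, 0.48 and 0.48, and SRPK1 and SRPK2 did not pass (0.09 and -0.0085). Among the splicing factors SRSF5, SRSF11 and SRSF4 rose by 0.64, 0.43 and 0.16, while SRSF7 and SRSF9 fell by 0.40 and 0.16. A rise of the dual specificity phosphatases outside the fixed lists, some of which switch off MAP kinases, also missed it (camera adjusted p = 0.217). Of these, 4 of 9 were higher, 3 lower and 2 not past the threshold. DUSP10 rose by 1.12 and DUSP7 by 0.80.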
